A study of Rattus norvegicus with 24 samples.

How the data were processed

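RNA was measured in 24 libraries of the medial preoptic area, a hypothalamic region, of Long Evans rats of both sexes. Per the labels, each library belonged to 1 sex and to either a control or an LBN group, with 6 libraries in each of the 4 groups. Per the labels' protocols, the tissue was dissected and frozen, RNA was extracted with trizol and a column kit, and polyA RNA libraries were made with the NEBNext Ultra kit. Libraries were named by group and a replicate number given in accession order, which pairs no libraries.

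Per the submitters' processing notes, the tools were FastQC 0.11.9, Trimmomatic 0.39, HISAT2 2.2.0, SAMtools 1.11, StringTie 2.1.2 and DESeq2 1.28.1, and the genome build was Rnor_6.0; the notes give no role or order for them. Per the file headers, StringTie 1.3.6 quantified each library against an assembly merged over the study, which differs from the version in the notes. Per the file headers, each deposited library file lists TPM, FPKM and per-base coverage for 91744 transcripts at 43597 gene loci, of which 41063 transcripts are reference transcripts and 50681 were assembled from the study's reads. Each deposited TPM column sums to the same total in every library, so these values carry no depth, and the authors applied no scaling between libraries to them per the file headers. A single gene symbol belonged to 17511 loci, 385 loci merged several symbols, 13837 had a clone name alone and 11864 had no name. In the deposited tables of the whole series only the gene names were used, and their 24 value columns, headed by bare numbers, were not used here. Depth was taken as coverage multiplied by transcript length, summed over the deposited transcripts of a library, in gigabases.

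The TPM of the transcripts of a locus was summed. Genes were tested where TPM was at least 0.5 in at least 6 libraries of a fit. Libraries were scaled by the median of ratios to the geometric mean, and log2(scaled TPM + 0.5) was fitted with limma 3.58.1 in R 4.3.3, with a trended prior variance, 2-sided moderated tests and Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of low genes. LBN was compared with control within each sex over 12 libraries. The difference of the LBN effect between the sexes, and the male against female comparisons in controls and in LBN, came from 1 fit of all 24 libraries with 4 group means. Males hold library numbers 1 to 12 and females 13 to 24, so sex and any processing that follows this numbering cannot be separated. The library titles are numbers that fall below or above 600. The labels do not say what these numbers mean. Values on each side of 600 are given separately, a choice made after the data were seen.

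Gene lists of pathways, cell types and neighbouring brain regions were fixed before the data were examined, as were the tests, the groups, the rule for named genes and most alternatives. Of 745 distinct list genes, 684 had a locus of their own and 23 occurred only in a merged locus. Symbols were matched without regard to case, with the locus of highest mean TPM taken for each symbol, and mitochondrial genes by name on the mitochondrial chromosome; both rules were set after the files were seen. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 37 lists of a comparison, with an estimated correlation and with fry beside it. The list of pituitary hormones had 2 tested members and was not tested.

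Named genes followed a fixed rule. In each LBN comparison and in male against female controls, it took up to 10 genes per direction past the threshold with a symbol and a mean TPM of at least 1, by size of change, or else the genes of smallest p up to 5 per direction. For the sex difference it took the 5 genes of smallest p per direction. From each list it took up to 4 members past the threshold. Where no member was past it and the list itself passed, it took the 3 of smallest p. Esr1, Pgr, Prlr, Oxtr, Gal, Crh, Th, Drd1, Drd2 and Cyp19a1 were reported in every LBN comparison; Nr3c1, also fixed, was not analysed here. Some genes that the rule took are not reported here.

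Alternatives covered the scaling, the pseudocount (0.1 and 1), the filter, a mean TPM of at least 1, limma-voom on read numbers estimated from coverage with an assumed read length of 75, library weights, a robust variance model, a tissue score over 6 lists as covariate, runs of consecutive title numbers as a random block, transcripts in place of genes, log2(FPKM + 1) of the deposited FPKM of reference transcripts, and each library left out in turn. Fits with the title number split, on each side of it, on reference transcripts summed by gene name, and without both female LBN libraries with the highest Y-linked signal were added after the data were seen. The counts of genes and lists were compared with 100 random regroupings of the same libraries, and with 100 that keep the numbers of libraries on each side of title number 600, which were added after the data were seen.

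The fit was tested on simulated log2 values with 200 changed genes per comparison, drawn only from genes with a mean TPM of at least 1. In the male fit such genes had a median standard error of 0.1514, against 0.1725 over all genes tested. The recovered shares therefore do not cover genes of lower TPM. Genes and libraries were drawn as independent, and the reading, scaling and filtering of the data were not part of this test. At a log2 change of 1, 67.2% of the changed genes were recovered for LBN in males, 76.1% for LBN in females, 56.7% for the sex difference, 76.1% for sex in controls and 71.6% for sex in LBN. At a log2 change of 0.5 the shares were 25.4%, 32.8%, 17.9%, 34.3% and 38.8%, and at 2 they were 93.9%, 95.5%, 78.8%, 98.5% and 95.5%, in the same order. Between 4.14% and 5.52% of the calls were false. In the data, the correlation within runs of consecutive title numbers was 0.338 in males and 0.146 in females. The simulated shares may therefore not hold for these libraries. The 60 pairs of libraries within a group held no identical pair, and each library was counted once, as labelled, which does not show that they came from separate animals. Other computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and the random block used statmod 1.5.0.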

Results

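Gene expression was measured by polyA RNA sequencing in the medial preoptic area, a hypothalamic region that governs male sexual behaviour and parental care, in a study of early life adversity in Long Evans rats. The labels give the treatment as LBN without spelling it out; in this field the letters usually stand for limited bedding and nesting, a rearing model of early adversity. Male control, male LBN, female control and female LBN groups held 6 libraries each. Summed coverage ranged from 3.27 to 5.98 gigabases per library, with 4.05 ± 0.262 (SD, n = 6) in male controls, 3.82 ± 0.382 (SD, n = 6) in male LBN, 5.00 ± 0.308 (SD, n = 6) in female controls and 4.92 ± 0.692 (SD, n = 6) in female LBN libraries. The labels do not say whether libraries came from separate animals or litters, so p-values measure the spread between these libraries. Values are TPM as mean ± SD over 6 libraries, fold changes are on the log2(TPM + 0.5) scale, and coordinates are those of Rnor_6.0. The TPM of the Y-linked genes matched the labelled sex in all 24 libraries, with Kdm5d at 17.0 to 21.5 TPM in males and 0 to 0.956 TPM in females.

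The first comparison asked whether LBN changed expression in the male preoptic area. Among the genes of smallest p, none past the threshold, those higher in LBN males included Il3ra, a subunit of the interleukin-3 receptor, at 29.3 ± 2.84 against 22.7 ± 0.725 TPM, and Galr3, a galanin receptor, at 7.12 ± 1.05 against 4.76 ± 0.648 TPM. Those lower included Nek6, a mitotic kinase, at 28.5 ± 2.63 against 39.0 ± 5.02 TPM, and Cfap100, a protein of cilia, at 10.4 ± 1.33 against 15.7 ± 2.28 TPM. Among marker groups, 21 of 22 markers of myelinating oligodendrocytes and 14 of 15 markers of meningeal fibroblasts stood higher in LBN males, and all 9 markers of cortical excitatory neurons stood lower. None of the individual genes passed the test.

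Of 25488 genes tested in males, 0 passed limma with Benjamini-Hochberg adjustment, 1190 had an unadjusted p under 0.05, and limma-voom called 0 with 1138. The smallest adjusted p in limma was 0.591, shared by Il3ra (chromosome 12, 18534767 to 18540472, log2 change 0.34, 95% confidence interval 0.19 to 0.49), Nek6 (chromosome 3, 22811685 to 22888598, log2 change -0.45, -0.64 to -0.27) and Cfap100 (chromosome 4, 122290701 to 122338407, log2 change -0.58, -0.83 to -0.34). Il3ra was above the control mean in 6 of 6 LBN libraries, and Nek6 and Cfap100 were below it in 6 of 6. The other genes of smallest p that stood higher were Myo1c (log2 0.37), Galr3 (0.52), Prtfdc1 (0.27) and Aamdc (0.69). Those that stood lower were Spata18 (log2 -0.44), Coq10b (-0.53) and Rabl2 (-0.46). The median half-width of the confidence interval over all genes was 0.37 on the log2 scale.

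The hormone receptor and neuropeptide genes chosen in advance did not pass in males. Prlr, the prolactin receptor, had a log2 change of -0.52 (95% confidence interval -1.03 to -0.0048), and Cyp19a1, the aromatase that makes estradiol from testosterone, of -0.58 (-1.29 to 0.13). Esr1, the estrogen receptor alpha gene, had -0.21 (-0.74 to 0.32), Pgr, the progesterone receptor, -0.09 (-0.54 to 0.35), and Oxtr, the oxytocin receptor, 0.25 (-0.24 to 0.74). For Gal, which encodes galanin, the change was -0.17 (-0.56 to 0.22), for Crh, the corticotropin-releasing hormone gene, -0.48 (-1.40 to 0.43), and for Th, the rate-limiting enzyme of dopamine synthesis, -0.03 (-0.57 to 0.51). The dopamine receptors Drd1 and Drd2 had -0.06 (-0.63 to 0.51) and 0.25 (-0.06 to 0.56). The list of gonadal steroid signalling had 6 of 17 members higher (camera, Benjamini-Hochberg adjusted p = 0.327; adjusted p = 0.558 with an estimated correlation).

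With camera's preset correlation 11 of 37 lists passed in males, 6 higher and 5 lower, and with an estimated correlation 0 passed. Myelinating oligodendrocyte markers had a median log2 change of 0.38 (camera, Benjamini-Hochberg adjusted p = 1.83e-09; adjusted p = 0.558 with an estimated correlation). Among them, Mbp, the myelin basic protein gene, was at 3648 ± 1166 against 2569 ± 757 TPM, Mobp at 568 ± 188 against 399 ± 118 TPM, and Bcas1 at 174 ± 53.0 against 128 ± 19.2 TPM. The median was 0.56 in libraries with title numbers below 600 (4 LBN, 4 control) and -0.0037 above 600 (2 LBN, 2 control). A score per library was the mean log2 value of the list members, centred over all 24 libraries. It was -0.636 and -0.664 in male control replicates 1 and 2. In the other male controls it was -0.0991 to 0.234, and in the LBN males -0.229 to 0.871. Leaving out 1 library at a time does not show how far the list rested on this pair of controls. Meningeal fibroblast markers had a median of 0.72 (adjusted p = 1.58e-09 in camera; adjusted p = 0.410 with an estimated correlation), with medians of 0.39 below and 1.35 above 600. Dcn, which encodes the matrix proteoglycan decorin, was at 7.90 ± 2.65 against 4.05 ± 0.901 TPM and was the 1 member that passed when adjusted over the list alone. Slc13a3 had a log2 change of 0.65 and Mgp of 0.35. Cortical excitatory neuron markers had a median of -0.52 (camera adjusted p = 6.10e-05; adjusted p = 0.410 with an estimated correlation), -0.19 below and -1.37 above 600. Of the members, 1 of 9 passed when adjusted over the list alone. Slc17a7, a vesicular glutamate transporter, was at 10.3 ± 11.1 against 42.0 ± 42.1 TPM and Lamp5 had a log2 change of -0.42, or -0.277 without male LBN replicate 6.

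Markers of nearby regions and barriers made up most of the other male lists that passed. Magnocellular and paraventricular markers stood lower in 7 of 7 members, with Oxt, the oxytocin gene, at 4042 ± 3162 against 6141 ± 2556 TPM, Sim1 at a log2 change of -0.63 and Otp at -0.60 (camera, Benjamini-Hochberg adjusted p = 0.0141; adjusted p = 0.558 with an estimated correlation). With any 1 of male LBN replicates 2, 3 and 4 and male control replicates 5 and 6 left out they did not pass in camera (highest adjusted p = 0.113). Without male LBN replicate 2 Sim1 was at -0.398 and Otp at -0.278. Arcuate, ventromedial and lateral hypothalamic markers stood higher in 9 of 10 (adjusted p = 0.0238 in camera; adjusted p = 0.649 with an estimated correlation), with Pomc at a log2 change of 2.11, Tbx3 at 0.80 and Hdc, the histamine-synthesising enzyme, at 0.46, and with male LBN replicate 6 far above the other LBN libraries in each. Without it Pomc was at 1.13, Tbx3 at 0.382 and Hdc at 0.005, and the list did not pass in camera, nor without male control replicate 1 (highest adjusted p = 0.949). Their median was -0.044 below and 1.48 above 600. Septal and basal forebrain cholinergic markers stood higher in 6 of 8 (camera adjusted p = 0.0305; adjusted p = 0.558 with an estimated correlation), with log2 changes of 1.20 for Ngfr and 1.09 for Chat, the acetylcholine-synthesising enzyme. Male LBN replicate 1 held 22.5 TPM of Chat and 44.7 TPM of Ngfr against means of 2.81 and 4.63 TPM in the other LBN males. Without it Ngfr was at 0.602 and Chat at 0.551. The list did not pass in camera without it, nor with any 1 of male LBN replicates 4 and 5 and male control replicates 1, 2 and 4 left out (highest adjusted p = 0.303). Choroid plexus markers stood higher in 8 of 12 (camera adjusted p = 0.0305; adjusted p = 0.410 with an estimated correlation), with Slc13a4 at 5.70 ± 2.95 against 2.24 ± 0.310 TPM, the 1 member past the threshold adjusted over the list alone, Enpp2 at a log2 change of 0.32 and Aqp1 at 0.58. They did not pass in camera with any 1 of male LBN replicates 1, 2 and 6 and male control replicates 1, 2 and 4 left out (highest adjusted p = 0.243). Aqp1 lay near the expression filter and was tested in only 6 of the 12 fits with 1 library left out. Ependymal and ciliary markers stood lower in 11 of 13 (camera adjusted p = 0.000526; adjusted p = 0.410 with an estimated correlation), among them Dynlrb2 (log2 -0.30), Ak7 (-0.24) and Ccdc153 (-0.46). Below and above 600 the medians were -0.67 and -0.39 for magnocellular, 1.23 and 0.059 for septal, 0.32 and 0.14 for choroid plexus, and -0.22 and -0.084 for ependymal markers. Male control replicates 1 and 2 had the lowest choroid plexus scores of the male libraries (-0.663 and -0.727). They also had the highest ependymal scores (0.312 and 0.309).

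The remaining male lists that passed were those of astrocytes, microglia and mitochondrially encoded genes. Astrocyte markers stood higher in 12 of 17 with a median of 0.06 (camera, Benjamini-Hochberg adjusted p = 0.0234; adjusted p = 0.649 with an estimated correlation), including the glutamate transporter Slc1a2 (log2 0.15), the gap junction gene Gja1 (0.20) and Ntsr2 (0.17). Their call ended in camera with any 1 of male LBN replicates 5 and 6 and male control replicates 3 and 4 left out (highest adjusted p = 0.65). Microglia markers stood lower in 13 of 17 with a median of -0.06 (camera adjusted p = 0.0305; adjusted p = 0.558 with an estimated correlation), including the complement gene C1qb (-0.21), Csf1r (-0.09) and Trem2 (-0.15). Theirs ended with any 1 of male LBN replicates 1, 3 and 4 and male control replicates 1, 2 and 6 left out (highest camera adjusted p = 0.197). Mitochondrially encoded genes stood lower in 7 of 8 (camera adjusted p = 0.00502; adjusted p = 0.558 with an estimated correlation), including ND1 (-0.21), ND2 (-0.29) and CYTB (-0.15), and did not pass without male LBN replicate 6 (camera adjusted p = 0.0561). Below and above 600 the medians were 0.0093 and 0.19 for astrocyte markers, -0.093 and -0.022 for microglia markers and -0.19 and -0.035 for mitochondrially encoded genes. None of the members of these 3 lists passed when adjusted over the list alone.

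The second comparison asked the same of females. In LBN females Cdh9, a cadherin of neuronal contacts, was at 6.05 ± 0.850 against 4.02 ± 0.146 TPM in controls, and Zfp612, a zinc finger gene, at 26.8 ± 5.39 against 15.2 ± 4.23 TPM. Naglu, a lysosomal enzyme that degrades heparan sulfate, was at 9.36 ± 0.648 against 11.7 ± 0.505 TPM. All 11 cortical excitatory neuron markers and 17 of 21 immediate early genes, which neuronal activity induces, stood higher in LBN females, and all 17 microglia markers stood lower. None of these genes passed on its own.

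Of 25566 genes tested in females, 0 passed limma with Benjamini-Hochberg adjustment, 1018 had an unadjusted p under 0.05, and limma-voom called 0 with 988. Cdh9 (chromosome 2, 66940057 to 67078784, log2 0.51, interval 0.30 to 0.73) and Naglu (chromosome 10, 88979383 to 88986867, log2 -0.32, -0.47 to -0.18) shared the smallest limma adjusted p of 0.806, with 6 of 6 LBN libraries on 1 side of the control mean in each. The other genes of smallest p that stood higher were Zfp612 (log2 0.81), Tfg (0.27), Popdc2 (0.54) and Emid1 (0.57). Lower were Phkg1, a phosphorylase kinase subunit (-0.67), Bard1 (-0.98) and Celf4, an RNA-binding protein of neurons (-0.35). The median half-width of the interval was 0.37. In the libraries with title numbers below 600 (4 LBN, 3 control), limma called 8 genes, and Drd1 had a log2 change of 1.56 (Benjamini-Hochberg adjusted p = 0.0214). In those above 600 (2 LBN, 3 control) it called 0 genes. Drd1 also belongs to the striatal projection neuron markers. Their score per library, the mean log2 value of the members centred over all 24 libraries, was 0.463 to 0.741 in LBN and -0.374 to -0.0149 in controls below 600. Above 600 the order turned, with 0.0564 and 0.280 in LBN and 0.115 to 1.235 in controls. Whether Drd1 changed apart from these markers was not tested.

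The genes chosen in advance did not pass in the 12 female libraries. Crh had a log2 change of 0.64 (95% confidence interval -0.10 to 1.38), above the control mean in 6 of 6 LBN libraries, at 33.3 ± 9.59 against 23.6 ± 12.5 TPM. Drd1 had 0.51 (-0.35 to 1.38), Drd2 0.18 (-0.31 to 0.67), Esr1 0.29 (-0.43 to 1.01), Gal 0.25 (-0.49 to 0.99) and Oxtr 0.04 (-0.34 to 0.43). Cyp19a1 had -0.10 (-0.68 to 0.48), Pgr 0.01 (-0.58 to 0.61), Prlr 0.02 (-0.56 to 0.61) and Th 0.01 (-0.86 to 0.88). Gonadal steroid signalling had 10 of 18 members higher (camera, Benjamini-Hochberg adjusted p = 0.638; adjusted p = 0.900 with an estimated correlation).

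**Figure D1:**
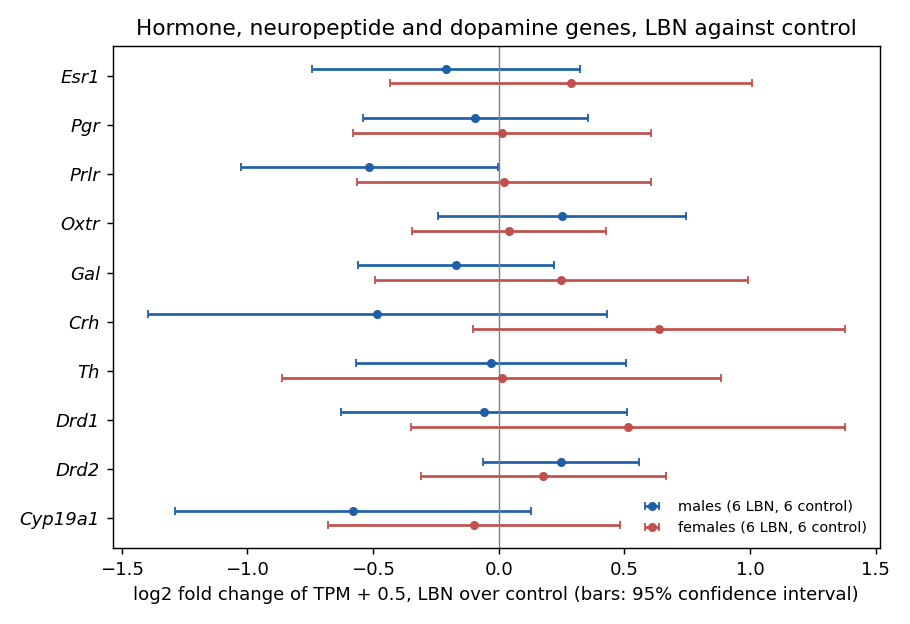
Log2 fold change of TPM + 0.5 in LBN over control (horizontal axis) for 10 genes chosen in advance, with points for males and females (6 LBN and 6 control libraries each) and bars for the 95% confidence interval. The female intervals all span 0, and among the male intervals that of Prlr lies below 0.

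With camera's preset correlation 9 of 37 lists passed in females, 3 higher and 6 lower, and with an estimated correlation 0 passed. Cortical excitatory neuron markers had a median log2 change of 0.76 (camera, Benjamini-Hochberg adjusted p = 6.02e-06; adjusted p = 0.717 with an estimated correlation), with 1.03 below and 0.06 above 600. Slc17a7 was at 112 ± 65.3 against 37.7 ± 38.1 TPM, and the transcription factors Neurod2 and Neurod6 had log2 changes of 1.55 and 1.53. Immediate early genes had a median of 0.28 (camera adjusted p = 6.32e-06; adjusted p = 0.717 with an estimated correlation), with 0.35 below and -0.03 above 600. Npas4 was at 2.40 ± 0.580 against 1.23 ± 0.837 TPM, Egr1 at 24.8 ± 6.24 against 15.9 ± 5.47 TPM, and Fosl2 had a log2 change of 0.37. Myelinating oligodendrocyte markers stood higher in 21 of 22 (camera adjusted p = 0.000791; adjusted p = 0.900 with an estimated correlation), with Enpp6 at 0.72, Tspan2 at 0.36 and Mal at 0.41. They did not pass in camera with any 1 of female LBN replicates 1 and 2 and female control replicate 2 left out (highest adjusted p = 0.152). Tspan2 was at 0.237 without female LBN replicate 1. Their median was 0.90 below and -0.56 above 600, where only 3 control libraries stand and female control replicate 4 held 6827 TPM of Mbp against 3874 and 2186 TPM in the others.

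The female lists that stood lower were markers of glia, meninges, blood, immunity and mitochondria. Microglia markers had a median of -0.20 (camera, Benjamini-Hochberg adjusted p = 4.80e-09; adjusted p = 0.717 with an estimated correlation), with Aif1 at a log2 change of -0.23, C1qc at -0.32, and medians of -0.06 below and -0.27 above 600. Meningeal fibroblast markers stood lower in 14 of 15 (camera adjusted p = 2.02e-05; adjusted p = 0.717 with an estimated correlation), among them Ogn (-0.76), Slc22a6 (-0.67) and the growth factor gene Igf2 (-0.71, or -0.472 without female LBN replicate 3). Interferon-response and antigen-presentation genes stood lower in 19 of 21 (camera adjusted p = 6.00e-05; adjusted p = 0.816 with an estimated correlation), with B2m, a subunit of MHC class I, at 202 ± 15.3 against 237 ± 41.1 TPM and Gbp2 at a log2 change of -0.32. The log2 change of B2m was -0.228, and -0.151 without female control replicate 6. Blood markers stood lower in 5 of 6 (camera adjusted p = 0.00166; adjusted p = 0.794 with an estimated correlation), with the haemoglobin gene Hbb at 105 ± 30.3 against 250 ± 240 TPM, Hba-a1 at -0.84 and Alas2 at -0.84. Female control replicate 4 held 725 TPM of Hbb against 154 ± 63.8 TPM in the other controls, and without it Hba-a1 was at -0.435, Alas2 at -0.55 and the list did not pass in camera (adjusted p = 0.083). Astrocyte markers stood lower in 15 of 17 (camera adjusted p = 0.00166; adjusted p = 0.900 with an estimated correlation), with Aqp4 at -0.28, Slc4a4 at -0.13 and Gfap at -0.47. Without female control replicate 6 Gfap was at -0.201 and Aqp4 at -0.171, and without either of female control replicates 4 and 5 the list did not pass in camera (highest adjusted p = 0.0613). Mitochondrially encoded genes stood lower in 8 of 8 (camera adjusted p = 0.00865; adjusted p = 0.900 with an estimated correlation), with ND5 at -0.16, CYTB at -0.13 and ND1 at -0.15. They did not pass in camera with any 1 of female LBN replicates 4 and 5 and female control replicates 4 and 5 left out (highest adjusted p = 0.44). Without female control replicate 4 the 3 genes were at -0.089, -0.068 and -0.058. Below and above 600 the medians were -0.057 and -0.86 for meningeal fibroblast markers, -0.045 and -0.31 for interferon-response genes, -0.25 and -1.15 for blood markers, -0.010 and -0.16 for astrocyte markers and 0.017 and -0.27 for mitochondrially encoded genes. In all 9 lists, 0 members passed when adjusted over the list alone.

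**Figure D2:**
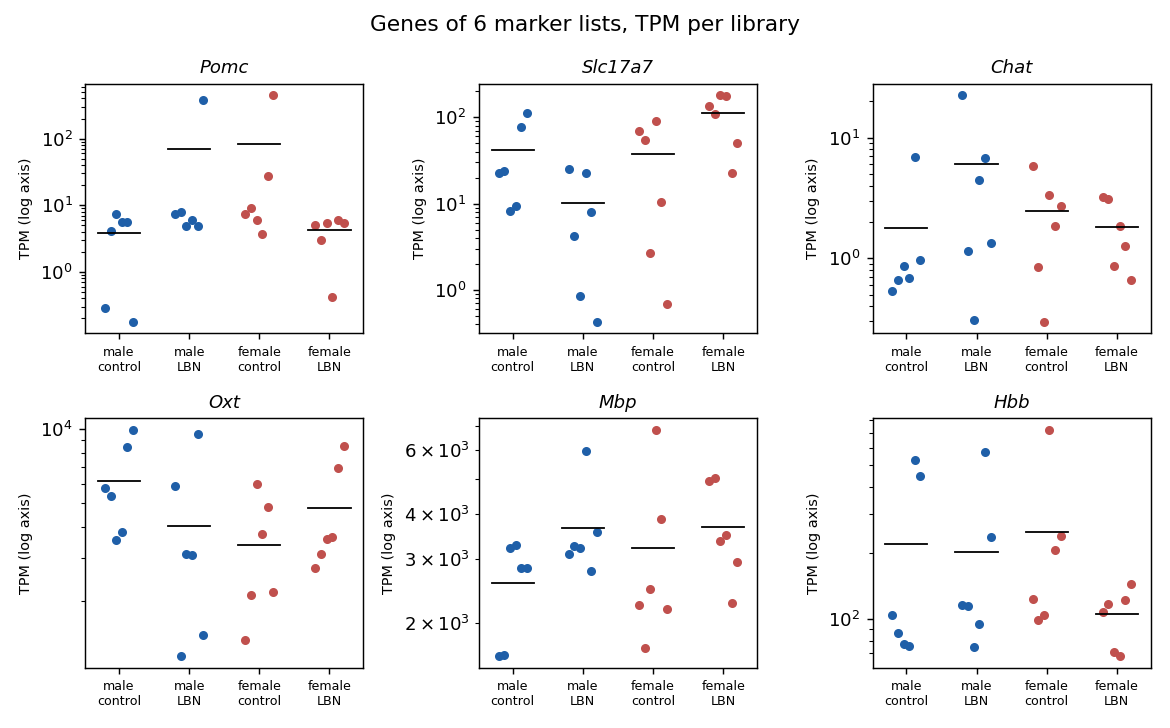
TPM on a log axis of Pomc, Slc17a7, Chat, Oxt, Mbp and Hbb in each of the 24 libraries by group, with points for libraries and lines for group means. Pomc reached 385 TPM in male LBN replicate 6 and 452 TPM in female control replicate 6, and Slc17a7 ranged from 0.430 to 181 TPM.

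The third comparison asked whether the LBN effect differed between the sexes. Zfp612 stood lower in LBN males (19.6 ± 3.62 against 22.5 ± 3.81 TPM) and higher in LBN females (26.8 ± 5.39 against 15.2 ± 4.23 TPM), and Ednrb, an endothelin receptor, stood higher in LBN males (92.0 ± 18.8 against 67.0 ± 10.1 TPM) and lower in LBN females (71.6 ± 7.41 against 87.7 ± 19.3 TPM, or 79.9 ± 4.15 TPM in the 5 controls other than replicate 6). The LBN effect on cortical excitatory markers was lower in males than in females in 11 of 11 members, and that on meningeal fibroblast markers was higher in 14 of 15. Single genes did not pass the interaction test.

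Of 27569 genes tested for the interaction, 0 passed limma with Benjamini-Hochberg adjustment, 1208 had an unadjusted p under 0.05, and limma-voom called 0 with 1167. The smallest adjusted p was 0.921 in limma, and the median half-width of the interval was 0.57. The genes of smallest p with a higher effect in males were Nt5c2 (difference of log2 changes 0.37), Cdk18 (0.94), Ednrb (0.72), Naglu (0.36) and Cmbl (0.63). Those with a lower effect in males were Zfp612 (-1.01, interval -1.501 to -0.53), Zim1 (-0.76), Dclk1 (-0.45) and Emid1 (-0.70). Across the 24795 genes tested in both sexes, which are not independent replicates, the log2 changes of males and females had Pearson r = -0.0199 and Spearman rho = -0.0275, and 48.9% had the same sign. Of 100 regroupings within each sex, Pearson r ranged from -0.245 to 0.147 and lay as far from their centre in 78.

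With camera's preset correlation 10 of 37 lists passed the interaction, 8 with a higher and 2 with a lower effect in males, and with an estimated correlation 0 passed. Meningeal fibroblast markers had a median difference of 1.106, with 8 of 15 past the threshold adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.73e-12; adjusted p = 0.267 with an estimated correlation). Among them were Dcn (1.36), Igf2 (1.61) and Ogn (1.497). Cortical excitatory neuron markers had a median difference of -1.277, with 5 of 11 past the threshold adjusted over the list alone (camera adjusted p = 6.42e-10; adjusted p = 0.267 with an estimated correlation), and Slc17a7 and Emx1 had differences of -4.83 and -1.277. Immediate early genes had a lower effect in males in 17 of 21 (camera adjusted p = 4.37e-05; adjusted p = 0.796 with an estimated correlation), with Nr4a1 at -1.21, Egr1 at -1.01 and Nr4a3 at -0.63. Astrocyte markers had a higher effect in males in 16 of 17, among them Aldh1l1 (0.38), Gfap (0.84) and Ntsr2 (0.22) (camera adjusted p = 0.000184; adjusted p = 0.796 with an estimated correlation). The difference for Gfap was 0.572 without female control replicate 6, which stood apart in it as male LBN replicate 6 did. Microglia markers did so in 16 of 17, with Aif1 at 0.39, Cx3cr1 at 0.29 and C1qc at 0.26 (camera adjusted p = 0.00576; adjusted p = 0.796 with an estimated correlation). The microglia list did not pass in camera with any 1 of female LBN replicate 3 and female control replicates 4 and 6 left out (highest adjusted p = 0.112). Cx3cr1 was at 0.185 without female LBN replicate 3.

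Vascular, antigen-presentation, hypothalamic and ribosomal lists made up the rest of the interaction. Interferon-response and antigen-presentation genes had a higher effect in males in 20 of 23, with the MHC class II genes Cd74 at 1.78, RT1-Ba at 1.17 and RT1-Da at 1.42 (camera, Benjamini-Hochberg adjusted p = 0.000561; adjusted p = 0.796 with an estimated correlation; camera adjusted p = 0.0501 without female control replicate 6). Endothelial markers did so in 9 of 12, with Cdh5 at 0.56, Vwf at 0.33 and Kdr at 0.42 (camera adjusted p = 0.0492; adjusted p = 0.802 with an estimated correlation). They were lost in camera with any 1 of 11 of the 24 libraries left out (highest adjusted p = 0.368), which were male LBN replicates 5 and 6, male control replicates 1 to 3, female LBN replicates 3 to 5 and female control replicates 4 to 6. Kdr was at 0.273 without female control replicate 6. Pericyte and smooth muscle markers did so in 8 of 8, with Cnn1 at 1.84, Abcc9 at 0.43 and Acta2 at 0.59 (camera adjusted p = 0.0323; adjusted p = 0.796 with an estimated correlation). These too were lost with any 1 of 11 left out (highest camera adjusted p = 0.55), which were male LBN replicates 1, 5 and 6, male control replicates 1 to 3, female LBN replicates 4 and 5 and female control replicates 1, 4 and 6. Abcc9 was at 0.236 without female control replicate 4 and Acta2 at 0.3 without male LBN replicate 5. Cnn1 lay near the expression filter and was tested in only 18 of the 24 fits with 1 library left out. Arcuate, ventromedial and lateral hypothalamic markers did so in 9 of 10, with Pomc at 4.23, Tbx3 at 1.38 and Fezf1 at 1.12 (camera adjusted p = 0.00552; adjusted p = 0.796 with an estimated correlation). Male LBN replicate 6 and female control replicate 6 stood apart in these 3 genes, and without either of them the list did not pass in camera (highest adjusted p = 0.205). Tbx3 was at 0.857 without the second and Fezf1 at 0.515 without the first. Cytosolic ribosomal proteins did so in 48 of 66 with a median of 0.03, with Rpl17 at 0.64, Rpl8 at 0.40 and Rpl35 at 0.11 (camera adjusted p = 0.0264; adjusted p = 0.802 with an estimated correlation). Ribosomal proteins were lost with any 1 of 8 left out (highest camera adjusted p = 0.378), which were male LBN replicates 4 to 6, male control replicates 1 and 2, female LBN replicates 3 and 4 and female control replicate 6. Within the title number split the median differences below and above 600 were 0.37 and 2.15 for meningeal fibroblast, -1.04 and -1.59 for cortical excitatory and -0.28 and -0.39 for immediate early genes. For astrocyte, microglia and endothelial markers the medians turned from -0.021, -0.039 and -0.064 below 600 to 0.34, 0.29 and 0.37 above it. For interferon-response genes they were 0.048 and 0.52, for pericyte markers 0.025 and 0.24, for arcuate, ventromedial and lateral hypothalamic markers 0.21 and 1.55 and for ribosomal proteins 0.0068 and 0.086.

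Male and female libraries were then compared within controls and within LBN. Sex-linked genes separated the sexes. On the Y chromosome, Eif2s3y, a translation initiation factor gene, was at 41.9 ± 3.96 TPM in control males and 0.303 ± 0.445 TPM in control females, and the histone demethylase gene Kdm5d at 19.0 ± 1.53 against 0.102 ± 0.165 TPM. On the X chromosome, Eif2s3 was at 51.2 ± 3.25 TPM in control males and 76.0 ± 1.90 TPM in control females, and Kdm6a, a histone demethylase gene, at 8.40 ± 1.05 against 12.9 ± 1.21 TPM. Striatal projection neuron markers stood lower in males in 13 of 13 members in controls and in LBN.

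In controls, limma with Benjamini-Hochberg adjustment called 19 of 27569 genes, 11 higher and 8 lower in males, of which 9 lie on Y, 6 on X and 4 elsewhere. Higher in males were Eif2s3y (chromosome Y, 914045 to 933699, log2 5.87, adjusted p = 1.65e-10), a Ddx3 gene on Y (1217800 to 1238420, log2 5.79, adjusted p = 1.18e-11) and Kdm5d (505996 to 629915, log2 5.06, adjusted p = 9.00e-14), each in 6 of 6 libraries. Lower in males were Eif2s3 (chromosome X, 63268037 to 63292547, log2 -0.56, adjusted p = 6.63e-07), Kdm6a (4806059 to 4945944, log2 -0.58, adjusted p = 0.000526) and Kdm5c (22302485 to 22355253, log2 -0.37, adjusted p = 0.0455). Kdm5c was lost in 19 of 29 alternatives, with adjusted p from 0.0251 to 0.864. Kdm6a was lost in 4 of 29 (highest adjusted p = 0.949) and Eif2s3 in 1 of 29 (highest adjusted p = 0.176). The lowest value belonged to an X-linked locus without a symbol, chosen after its values were seen (74341628 to 74345042), at 0.429 ± 0.437 TPM in control males and 80.1 ± 16.9 TPM in control females (log2 -6.53). It and another X call, AABR07039356.2 (74324212 to 74341527), lie within the span of a further X call, LOC680227 (74304292 to 74347016). All were lower in males, so these X calls may not be separate genes. Among the 4 calls elsewhere, MSTRG.30147 lies on KL568157.1 and not on a numbered chromosome. The genes of smallest p that did not pass were Pcdh18 (log2 0.59, adjusted p = 0.0544) and Sytl5 (0.56, adjusted p = 0.0783) on the higher side, and Col12a1 (-0.61, adjusted p = 0.053) and Lrrc10b (-0.81, adjusted p = 0.0611) on the lower side.

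In LBN, limma with Benjamini-Hochberg adjustment called 20 genes, 11 higher and 9 lower in males, of which 16 were also called in controls, all in the same direction (0.00439 and 0.00261 shared genes would be expected of independent lists, for higher and lower). Outside the sex chromosomes, Emid1, an extracellular matrix gene, was lower in males, at 6.88 ± 0.861 against 11.8 ± 2.16 TPM (log2 -0.72, adjusted p = 0.024). The rule for named genes did not take Emid1 in this comparison. The count was 39 without female LBN replicate 5 and 33 with only the 12 LBN libraries. It was 223 in libraries with title numbers below 600 and 9 above 600.

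**Figure D3:**
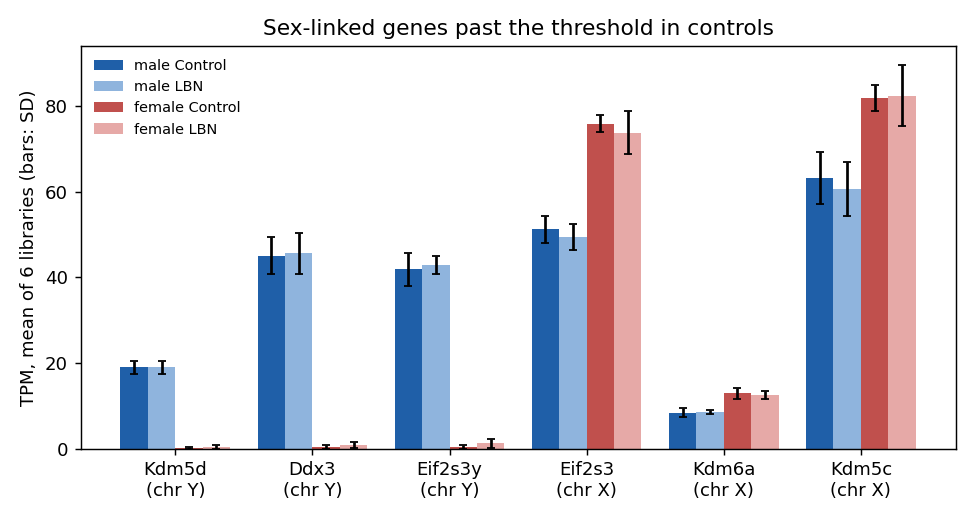
TPM of 6 sex-linked genes that passed in controls (vertical axis), as group means of 6 libraries with bars for the SD. Kdm5d, Ddx3 and Eif2s3y on Y were near 0 in females, and Eif2s3, Kdm6a and Kdm5c on X were higher in females.

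With camera's preset correlation 10 of 37 lists passed between the sexes in controls and 7 in LBN, and with an estimated correlation 0 passed in either. The test fry called 2 and 3. Striatal projection neuron markers had a median of -0.59 in controls (camera, Benjamini-Hochberg adjusted p = 7.81e-10; adjusted p = 0.222 with an estimated correlation; fry adjusted p = 0.0351), with 7 of 13 past the threshold adjusted over the list alone. In LBN the median was -0.67 (camera adjusted p = 3.55e-13; adjusted p = 0.0735 with an estimated correlation; fry adjusted p = 0.00627), with 10 of 13. In controls the median was -0.22 below and -0.74 above 600, and in LBN -0.81 and -0.33. Gpr6 and Lrrc10b had log2 differences of -0.64 and -0.81 in controls. Sex chromosome genes passed in fry with adjusted p = 4.47e-07 in controls and 1.00e-05 in LBN, but not in camera (adjusted p = 0.146 and 0.274); 3 of the 7 stood higher and 4 lower in males. Their median was -0.31 and their mean 2.13 in controls. Cortical excitatory markers stood lower in LBN males in 11 of 11, with 9 past the threshold adjusted over the list alone (camera adjusted p = 5.62e-12; adjusted p = 0.106 with an estimated correlation; fry adjusted p = 0.0163), with medians of -1.64 below and -0.62 above 600. Among them, Slc17a7 was at 10.3 ± 11.1 against 112 ± 65.3 TPM, and Nrgn, a postsynaptic calmodulin-binding protein, had a log2 difference of -1.281.

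Immediate early genes stood lower in LBN males in 19 of 21, with 8 past the threshold adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.24e-09; adjusted p = 0.298 with an estimated correlation), led by Nr4a1 (-1.22), Egr4 (-1.40) and Egr1 (-1.04), with medians of -0.53 below and -0.11 above 600. In LBN males interferon-response and antigen-presentation genes stood higher in 22 of 23, with B2m at 0.34 and Gbp2 at 0.49 (camera adjusted p = 4.13e-06; adjusted p = 0.721 with an estimated correlation). Meningeal fibroblast markers stood higher in LBN males in 14 of 15, with Igf2 at 0.98, Igfbp2 at 0.78 and Mgp at 0.63 (camera adjusted p = 3.23e-05; adjusted p = 0.721 with an estimated correlation), and lower in control males in 13 of 15, with Dcn at -0.76 (-0.45 without female control replicate 6), Col1a2 at -0.95 and Slc22a6 at -1.02 (camera adjusted p = 3.70e-05; adjusted p = 0.703 with an estimated correlation). Astrocyte and microglia markers stood higher in LBN males in 14 of 17 each, with Gja1 at 0.26 and Cx3cr1 at 0.35 (camera adjusted p = 0.0127 and 0.0189; adjusted p = 0.721 with an estimated correlation for both). Both lists were lost in camera with any 1 of male LBN replicates 5 and 6 and female LBN replicates 3 and 4 left out, and the microglia list also without male LBN replicate 2 (highest adjusted p = 0.345 for astrocyte and 0.189 for microglia markers). Below and above 600 the medians in LBN were 0.0775 and 0.63 for interferon-response genes, 0.036 and 1.73 for meningeal fibroblast, 0.017 and 0.22 for astrocyte and 0.135 and 0.037 for microglia markers. In controls, thalamic neuron markers stood lower in males in 8 of 9, with Rgs16 at -0.82, Prkcd at -1.15 and Synpo2 at -0.97 (camera adjusted p = 0.0183; adjusted p = 0.703 with an estimated correlation). Without female control replicate 4 these log2 differences were -0.595, -0.586 and -0.538, and the list did not pass in camera without it or without female control replicate 5 (highest adjusted p = 0.403).

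The other lists that passed in controls were those of choroid plexus, ependymal, neuropeptide receptor, arcuate, glucocorticoid-responsive, ribosomal and mitochondrial genes. Choroid plexus markers stood lower in males in 11 of 14, with the anti-ageing hormone gene Kl at a log2 difference of -1.26 (interval -1.81 to -0.71), the 1 member past the threshold adjusted over the list alone, Slc13a4 at -0.90 and Aqp1 at -0.92 (camera, Benjamini-Hochberg adjusted p = 0.0212; adjusted p = 0.703 with an estimated correlation). They were lost with any 1 of male control replicate 2 and female control replicates 4, 5 and 6 left out (highest camera adjusted p = 0.0944). Ependymal and ciliary markers stood higher in 12 of 13, with Ccdc153 at 0.54 and Tekt1 at 0.31, while Rarres2 was at -0.40 (camera adjusted p = 0.0193; adjusted p = 0.703 with an estimated correlation). Without female control replicate 4 Ccdc153 was at 0.346, Tekt1 at 0.086 and the list did not pass (camera adjusted p = 0.889). Without female control replicate 6 Rarres2 was at -0.22. Neuropeptide receptors stood higher in 20 of 30, with the somatostatin receptors Sstr1 at 0.50 and Sstr2 at 0.31 and the melanocortin receptor Mc4r at 0.64 (camera adjusted p = 0.0341; adjusted p = 0.703 with an estimated correlation). That call was lost with any 1 of male control replicates 5 and 6 and female control replicate 4 left out (highest camera adjusted p = 0.598). Arcuate, ventromedial and lateral hypothalamic markers stood lower in 9 of 10, with Kiss1, the kisspeptin gene, at 4.54 ± 1.04 against 25.7 ± 19.5 TPM, Pomc at -2.52 and Nptx2 at -0.53 (camera adjusted p = 0.0391; adjusted p = 0.722 with an estimated correlation). Female control replicate 6 held 452 TPM of Pomc against 10.7 ± 9.42 TPM in the other female controls. The list did not pass in camera without it, nor without male control replicates 1, 2 or 3 (highest adjusted p = 0.872). Pomc was at -1.578 without female control replicate 6. Glucocorticoid-responsive genes stood lower in 17 of 20, with Cdkn1a at -0.30, Pdk4 at -0.27 and Ddit4 at -0.17 (camera adjusted p = 0.0467; adjusted p = 0.703 with an estimated correlation). Of the 12 control libraries 7 left out 1 at a time ended this call (highest camera adjusted p = 0.491), male control replicates 1 to 4 and female control replicates 1, 4 and 5. Cytosolic ribosomal proteins stood lower in 51 of 66, with Rps23 at -0.20, Rps21 at -0.29 and Rpl27a at -0.14 (camera adjusted p = 0.00013; adjusted p = 0.703 with an estimated correlation). Mitochondrially encoded genes stood higher in 8 of 8, with ND6 at 0.16, COX2 at 0.15 and ND5 at 0.13 (camera adjusted p = 0.0212; adjusted p = 0.704 with an estimated correlation). The mitochondrial list was lost with any 1 of male control replicates 2, 3 and 4 and female control replicates 3 and 6 left out (highest camera adjusted p = 0.13). ND6 was at 0.090 without female control replicate 6, and COX2 at 0.1 and ND5 at 0.084 without male control replicate 2. Below and above 600 the medians in controls were -0.12 and -1.10 for thalamic, -0.36 and -0.62 for meningeal fibroblast, -0.16 and -0.31 for choroid plexus and 0.055 and 0.35 for ependymal markers. They were -0.025 and 0.23 for neuropeptide receptors, -0.093 and -0.15 for glucocorticoid-responsive genes, 0.32 and -0.17 for mitochondrially encoded genes, 0.0016 and -0.57 for arcuate, ventromedial and lateral hypothalamic markers and -0.031 and -0.049 for ribosomal proteins.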

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

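The list comparisons between the sexes were planned, and the tests of explanations and of regroupings in this part were chosen after the results were seen. A library was singled out where its gap to the nearest library of its group was large against the range of the group. Of 396 combinations of gene and group 40 met this, and 10 lay in female control replicate 6, 7 in male LBN replicate 6 and 5 in male control replicate 5. A rate of 1 in 20 groups, or 20 of these, would hold only for independent, normally distributed values. TPM was used here without logarithms, genes of a list moved together, and many were chosen from these data. The count of 40 can therefore not be read against 20. Over the 7850 genes of higher mean TPM used for the log2 spread, female control replicate 4 stood farthest from the other 23 libraries. Its median log2 spread was 0.303 (0.228 to 0.373). Without this library 1466 genes had an unadjusted p under 0.05 for LBN in females against 1018 with it, with 0 past the threshold in limma in both.

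In male LBN replicate 6 the gap took a share of the range of 0.992 for Pomc (385 TPM against 6.2 ± 1.38 in the others), 0.914 for Tbx3, 0.946 for Hdc, 0.963 for Fezf1, 0.684 for Oxtr, 0.626 for Gfap and 0.806 for Nrgn, each the highest of the group. In female control replicate 6 it was 0.948 for Pomc (452 TPM against 10.7 ± 9.42), 0.936 for Tbx3, 0.8 for Fezf1, 0.834 for Gfap, 0.686 for Aqp4, 0.794 for Ednrb, 0.857 for Cmbl, 0.789 for Dcn, 0.699 for RT1-Ba and 0.626 for Col1a2, again the highest. Pomc, Tbx3 and Fezf1 mark arcuate and ventromedial neurons. In male control replicate 5 it was 0.719 for Tbx3, 0.771 for Ngfr, 0.934 for Chat, 0.878 for Rgs16 and 0.802 for Synpo2, and in male LBN replicate 1 it was 0.761 for Ngfr, 0.707 for Chat and 0.707 for Rpl8, all the highest. In male LBN replicate 2 Ccdc153 (0.66) and Ddx3 (0.659) were highest, in male LBN replicate 4 Mbp (0.752) and Mobp (0.68), and in male LBN replicate 5 Acta2 (0.83). In female control replicate 4 Npas4 (0.648), Hbb (0.778), Hba-a1 (0.794) and Abcc9 (0.727) were highest, and in female control replicate 3 Zim1 (0.636). In female LBN replicate 5 Aqp4 was lowest (0.829) and Fezf1 (0.677) and Rpl17 (0.629) were highest, and in female LBN replicate 6 Crh (0.711) and Abcc9 (0.793) were highest.

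The LBN effect differed between the sexes in camera at the preset correlation for 10 lists. The Benjamini-Hochberg adjusted p was 2.73e-12 for meningeal fibroblast, 6.42e-10 for cortical excitatory, 4.37e-05 for immediate early, 0.000184 for astrocyte, 0.000561 for interferon-response, 0.00552 for arcuate, ventromedial and lateral hypothalamic, 0.00576 for microglia, 0.0264 for ribosomal, 0.0323 for pericyte and 0.0492 for endothelial lists. With an estimated correlation the adjusted p was 0.267 for the meningeal fibroblast and cortical excitatory lists, 0.802 for the ribosomal and endothelial lists and 0.796 for the other 6.

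Regroupings of the same libraries do not exclude chance for any count of lists. In males 41 of 100 splits, the real one included, gave as many as the real 11 lists, and the highest of the others gave 22. In females it was 69 of 100 (real 9, highest other 21), for the sex difference 50 of 100 (real 10, highest other 21), for sex in controls 69 of 100 (real 10, highest other 20) and for sex in LBN 74 of 100 (real 7, highest other 19). For genes, LBN in males, LBN in females and the sex difference had a real count of 0, which each of the 100 splits must reach. This count therefore says nothing about chance there (highest others 61, 9 and 4). For genes with an unadjusted p under 0.05, 39, 44 and 47 of 100 splits reached the real count, in the same order. A split of the male libraries that calls 61 genes points to a structure of the libraries. For sex in controls 1 of 100 splits reached the real 19 genes (highest other 5), and for sex in LBN 1 of 100 reached the real 20 (highest other 10). In each, 9 calls lie on Y and 6 on X and follow the sex labels, so this outcome was largely fixed in advance. The calls outside X and Y, 4 in controls and 5 in LBN, were not counted apart, so chance is not excluded for them. Splits that keep the numbers on each side of title number 600 did not exclude chance for lists either. As many lists came from 11 of 100 in males (highest other 14), 60 in females (18), 42 for the sex difference (18), 47 for sex in controls (18) and 58 for sex in LBN (18). Among these the highest count of genes in males was 1, and 1 of 100 reached the real count of genes for sex in controls (highest other 2) and in LBN (highest other 3). Both real counts again include the X and Y calls. For genes with an unadjusted p under 0.05, 5 of 100 of these splits reached the real count in males, 35 in females and 29 for the sex difference.

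The marker lists that passed in the LBN comparisons belong largely to neighbouring regions, glia, meninges and blood. A candidate explanation is that libraries held unequal shares of neighbouring tissue or cell types. Within groups, the members of the lists that passed had a median correlation of 0.56. It was 0.178 in lists that did not pass and -0.00718 in random lists of the same sizes. Of the 20 lists that passed, 19 lay above the highest random list (0.0579). Lists whose members move together pass more readily at camera's preset correlation, so these values do not decide. Unequal shares and an effect of LBN on these cell types both stay open.

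Y-linked transcripts were measured in some female libraries, up to 4.66% of the male mean in female LBN replicate 2 and 4.3% in female LBN replicate 1. Reads of X-linked copies placed on the Y genes are argued against, since the highest female library stood 5.2 times above the median in Y-linked TPM while the X copy Eif2s3 ranged by 1.2 times. RNA or reads of male libraries mixed in stay open, since the shares of the abundant Y genes lay within 1.74 times of each other in these 2 libraries but differed by 3.1 times in female LBN replicate 4, beyond the factor of 3 set for the test. The share was 2.26 ± 1.99% (SD, n = 6) in female LBN and 0.682 ± 0.807% (SD, n = 6) in female controls, with an exact 2-sided permutation p = 0.117 over 924 regroupings. No biological explanation was tested.

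Some pairs of libraries of a group lay close, with a log2 spread as small as 0.106 over the same 7850 genes. The median was 0.201 within groups, 0.197 between groups of 1 sex and 0.2 between sexes. Pairs from different groups lay as close as 0.133 (male control replicate 4 and male LBN replicate 3) and 0.139 (female control replicate 5 and female LBN replicate 6). Animals with consecutive title numbers could share a litter or a dissection, and an exact 1-sided test over choices of pairs gave p = 0.156. Libraries with neighbouring library numbers could have been prepared together, and a 1-sided permutation test gave p = 0.192. The exact test covered title numbers below 600 only. There, pairs with consecutive titles were the closest of their group in both male groups. They ranked 2 of 3 in female controls (0.157 against 0.154 for the others) and 5 of 6 in female LBN (0.198 against 0.158). The spread was 0.182 for neighbouring and 0.188 for other library numbers, so neither explanation was decided. With runs of consecutive titles as a random block, the correlation within runs was 0.338 in males and 0.146 in females. With this block 785 genes in males and 901 in females had an unadjusted p under 0.05, against 1190 and 1018 without it. No biological explanation was tested.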

How the results depend on the processing

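The fits with the title number split, by gene name and without both female LBN libraries with Y-linked signal were chosen after the data were seen, and the others were planned. No paired analysis was possible because the labels give no number shared between groups. The counts of genes stayed within 1.5 times of those reported in 17 of 19 alternatives for LBN in males, 16 of 20 for LBN in females, 15 of 17 for the sex difference, 16 of 17 for sex in controls and 14 of 18 for sex in LBN, apart from single libraries left out. Across genes, r between the effects in males and females ranged from -0.0312 to 0.00151. Over 6385 values of named genes under alternatives 98 had the other sign, none of them for a gene that had passed, 41 lost and 30 gained the threshold. Over the lists that passed 276 values lost the threshold, and 1 turned to the other direction while past it. Medians that changed sign between sides of 600 without passing in the other direction are not in that count. Fits on 1 side of 600 use fewer libraries, and where no cause is given the cause was not tested.

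With an estimated correlation 0 lists passed in each of the 5 comparisons. With fry 0 passed for LBN in males, LBN in females and the sex difference, 2 for sex in controls and 3 for sex in LBN. With limma-voom 17 lists passed in males. On libraries with title numbers below 600, limma called 2 genes for LBN in males (AABR07004112.1 and Rpl30, chosen after their values were seen, as are all genes named here), 8 in females, 3 for the sex difference (Diras2, Dclk1 and AABR07004112.1) and 223 for sex in LBN. Above 600 it called 2 in males (Ptgds and Fbll1), 1 for the sex difference (MSTRG.19419) and 9 for sex in LBN, and 15 lists passed in females and 17 for the sex difference. With only title numbers above 600, 1 result (list myelinating oligodendrocyte markers: LBN against control in females) turned to lower in 5 libraries, of which female control replicate 4 stood apart in Mbp, with a camera adjusted p of 3.7e-06. On reference transcripts by gene name 1 gene was called in females (LOC100363782), 10 for sex in controls and 10 for sex in LBN. In females 5 transcripts were called in place of genes (ENSRNOT00000042711, MSTRG.16874.1, MSTRG.16874.3, MSTRG.23480.2 and MSTRG.3088.4), and 1 by log2(FPKM + 1) (ENSRNOT00000042711). With only the 12 libraries compared, 6 lists passed for sex in controls and 33 genes for sex in LBN. Without both female LBN libraries with Y-linked signal, 11 lists passed for sex in LBN.

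With each library left out in turn, limma called 0 to 1 genes for LBN in males, 0 to 2 in females, 0 to 1 for the sex difference, 18 to 22 for sex in controls and 16 to 39 for sex in LBN. The call in males came without male control replicate 2 (RGD1566265) or replicate 6 (AABR07004112.1), the 2 in females (MSTRG.28703 and AABR07035107.1) without female control replicate 1, the 1 of the sex difference (MSTRG.5413) without male LBN replicate 2, and the 39 without female LBN replicate 5. Lists ranged from 9 to 14 in males, 8 to 15 in females (15 without female LBN replicate 6), 4 to 14 for the sex difference (4 without female control replicate 6), 6 to 15 for sex in controls (6 without male control replicate 2, 15 without female control replicate 2) and 5 to 11 for sex in LBN (11 without male LBN replicate 3). Of the 47 lists that passed over the comparisons, 26 lost the threshold without at least 1 library. For 4 of them this was a single one: mitochondrially encoded genes in males (male LBN replicate 6), blood markers in females and ependymal markers in controls (female control replicate 4), and interferon-response genes in the sex difference (female control replicate 6). Of 203 log2 changes of named genes, 57 shrank by more than 1.5 times or changed sign without 1 library. Among these were Crh, Esr1 and Gal in females and Ccdc153 and Tekt1 in controls without female control replicate 4, Oxtr, Crh and Cyp19a1 in males without male LBN replicate 6, and Sim1 and Otp in males without male LBN replicate 2. In males Esr1 was at -0.067 without LBN replicate 1. Male Pgr, Th and Drd1 changed sign, to 0.01 without LBN replicate 5, 0.005 without LBN replicate 3 and 0.037 without control replicate 6. Depth of 3.27 to 5.98 gigabases and 6 libraries per group left a median standard error of 0.17 for LBN in either sex.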

Other observations

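All tests in this part were chosen after the data were seen. Libraries with title numbers above and below 600 differed in single genes within each sex, and in marker lists in camera at the preset correlation but in none with an estimated correlation. In males, Hbb was at 446 TPM above 600 and 93.2 TPM below (log2 2.22), the growth factor binding protein gene Igfbp4 at 8.98 and 2.89 TPM (1.49), and the lysosomal enzyme gene Idua at 47.0 and 84.1 TPM (-0.81). In females, Pmch, which encodes melanin-concentrating hormone of the lateral hypothalamus, was at 72.2 and 0.498 TPM (5.25), Pla2g7 at 33.6 and 14.2 TPM (1.17), Nts, the neurotensin gene, at 35.4 and 91.6 TPM (-1.32), and Lhx8, a transcription factor of basal forebrain neurons, at 6.21 and 15.9 TPM (-1.18). Limma with Benjamini-Hochberg adjustment called 1516 genes in males (4 libraries above, 8 below), 594 higher and 922 lower above 600, and 36 in females (5 above, 7 below), 26 higher and 10 lower. In males 81.5% of the higher and 42.3% of the lower genes had a symbol, against 50.7% of those tested. Reference transcripts held 70.2 to 70.4% of TPM in males above 600 and 68.3 to 69.1% below. Genes with TPM of at least 0.5 numbered 23967 to 24360 in males above 600 and 24760 to 25541 below. The cause of these differences between male libraries was not tested.

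In males above 600, immediate early genes had a median log2 difference of 0.52 with 9 of 21 members past the threshold (camera, Benjamini-Hochberg adjusted p = 3.21e-11; adjusted p = 0.0805 with an estimated correlation), and blood markers of 1.76 with 5 of 6 (camera adjusted p = 3.38e-10; adjusted p = 0.0805 with an estimated correlation). Astrocyte markers had a median of 0.25 with 8 of 17 (camera adjusted p = 2.14e-10; adjusted p = 0.0805 with an estimated correlation) and endothelial markers of 0.35 with 5 of 12 (camera adjusted p = 1.61e-08; adjusted p = 0.0805 with an estimated correlation). In females, thalamic neuron markers had a median of 1.67 with 1 of 9 past the threshold (camera adjusted p = 1.56e-10; adjusted p = 0.324 with an estimated correlation). Their score per library above 600 was 2.36 and 1.61 in female control replicates 4 and 5 and 2.01 in female LBN replicate 6. It was 0.039 in female LBN replicate 5 and -0.30 in female control replicate 6. Below 600 the female scores were -0.611 to -0.385. Immediate early genes in females had a median of -0.031 (camera adjusted p = 0.485; adjusted p = 0.811 with an estimated correlation), and the difference between the sexes was not tested. The labels do not say what the title numbers mean.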
